A study of Mus musculus with 14 samples.

How the data were processed

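Small intestinal organoids from a female Lgr5GFPDTR/+ mouse were studied by ChIPmentation, a form of chromatin immunoprecipitation in which the Tn5 transposase adds sequencing adapters to chromatin while it is bound to the antibody. Antibodies were against H3K27ac, the acetylation of histone H3 at lysine 27 that marks active promoters and enhancers, and against the transcription factor ONECUT2. Per the labels, 3 H3K27ac and 3 ONECUT2 libraries came from organoids given RANKL (100 ng/mL, harvested at day 6), the same numbers came from organoids kept in ENR medium (EGF, Noggin and R-spondin 1), and each condition had 1 input library. Per the labels' protocols, the RANKL arm was first kept for 3 days with 3 µM CHIR99021, an activator of Wnt signalling, and 1.5 mM valproic acid, an inhibitor of histone deacetylases, and then had a day in ENR alone before RANKL. The protocols describe the control as ENR medium, so each comparison is of the whole M cell protocol against ENR medium and not of RANKL alone. Replicates are 3 independent differentiation experiments, and the labels' descriptions number the libraries of both arms by experiment. All came from the line of 1 mouse, so p-values measure the spread between differentiation experiments.

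The authors' H3K27ac count table holds raw whole-number read counts for 55050 non-overlapping regions of 2000 bp, 53 of them on unplaced scaffolds. A second H3K27ac table, headed as normalised, was deposited by the authors as a score. Its values equal the logarithm of the count plus 1, centred and scaled to an SD of 1 within each library, to within 5e-06, and it was used in 1 alternative only. For ONECUT2, the authors' deposited table of a comparison made with DiffBind, per the submitters' processing notes, lists sites (401 bp but for 1 wider site) with the log2 mean normalised read count per condition and a log2 fold change, per the file headers. The authors' deposited table also gives a p-value and an adjusted p (FDR) per site. Only sites with an FDR of up to 0.0496 are listed, 7268 in number, and the ranks of the listed p-values imply that 7734 sites were tested. The listed fold changes are slightly smaller than the differences of the listed means, and the table holds no values per library. The genome build was mm10, per the submitters' processing notes. The aligner, peak caller, duplicate handling, normalisation of the ONECUT2 table and version of DiffBind are not given in the sources used here. The 2 input libraries and per-library ONECUT2 values were not analysed here.

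H3K27ac totals over the regions were 5434172, 9160267 and 5578062 reads in control replicates 1 to 3 and 2745451, 3252533 and 3902301 reads in RANKL replicates 1 to 3. Pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 1.79 to 2.06, so no library was counted as a repeat of another. Coordinates are printed as deposited. Each H3K27ac region has an end 2000 above its start, which leaves open whether its start is counted from 0.

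Region counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM normalisation, the filterByExpr filter, which kept 54765 regions, and Benjamini-Hochberg adjusted p under 0.05. Genes came from a RefSeq gene table of the matching mouse assembly with gene spans and no strand. Regions were assigned to the nearest of 21883 protein-coding gene spans within 100 kb. This replaced the planned assignment to start sites, and regions within 2 kb of either gene end replaced promoters. It placed 86.6% of regions at 16100 genes, with a median of 2 regions per gene, and 56.3% of regions overlapped a gene span. Exons and introns were not resolved. Counts of all regions of a gene were summed per library and tested in the same way, over 16035 genes. The nearest gene need not be the gene a region acts on. CPM values are counts of a region, or of all regions of a gene, scaled to the TMM-normalised library size. TMM factors were computed separately for regions and for genes, so values of the 2 levels are not on one scale. Against library size only, TMM moved the median log2 fold from 0.153 to 0.057 over regions and from -0.042 to 0.013 over genes. Spib, which has 1 region, had a log2 fold of 2.01 as a region and 2.17 as a gene.

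In all, 20 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists. Of their 427 entries, 3 had no match in the gene table. Some genes are on more than 1 list, among them Spib (M cell and tuft), Clu (M cell and fetal), Ccl9 (M cell and goblet) and Apoa4 (enterocyte and proximal enterocyte). H3K27ac at ONECUT2 sites was tested with camera over the regions that overlap a listed site by at least 1 bp, and the overlap with Fisher's exact test over regions, which are not independent replicates. List members near ONECUT2 sites were counted against 10000 random draws of genes matched on their number of regions and H3K27ac level. Genes were named by a rule written before the data were examined. It takes Onecut2, Gp2, Spib, Sox8, Tnfrsf11a and Lgr5, the 10 genes of smallest adjusted p in each direction with an absolute log2 fold of at least 1 and no overlap between the groups, and up to 3 members per list in the direction of most of its calls. It also takes the 5 regions of smallest adjusted p and the 8 ONECUT2 sites of smallest FDR in each direction, and up to 3 sites of smallest FDR at genes of the M cell, enterocyte, stem cell and transcription factor lists. Keeping a tie at the last place, and naming Onecut1 regions, the sites at Lgr5 and Tnfrsf11a and the members that make up counts of 5 or fewer, were decided after the values were seen.

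On simulated counts with the real library sizes, the region test over 54560 regions recovered 21.2% of 1.5-fold, 52.2% of 2-fold and 98.5% of 4-fold changes, with 4.2% false calls. The gene test over 16014 genes recovered 61.2%, 89.6% and 100% at these folds, with 2.3% false calls. Only 66 or 67 features were changed at each fold, far fewer than were called in the data, and recovery after adjustment depends on that share. The labels give an experiment number to each H3K27ac library, and the same numbers in both arms were read as pairs. Deviations of same-numbered libraries from their group means had correlations of 0.014, -0.027 and -0.007 across regions, against -0.034 to 0.047 for other pairs. The fit without the experiment as a block was the main one and the blocked fit an alternative. Other alternatives were DESeq2 1.42.0, other scalings, filters and thresholds, a minimum fold of 1.5, loess offsets that remove the trend of fold with signal (span 0.3), leaving out each library, other gene assignments, an estimated correlation and fry for the lists, and libraries thinned to the shallowest total. Motif tests and corrections for GC content needed a genome sequence and were not run. Calculations outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.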

Results

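H3K27ac was profiled in 3 RANKL-treated and 3 control organoid cultures, and ONECUT2 binding in 3 and 3 libraries, with replicates from 3 independent differentiation experiments. RANKL is the cytokine that drives differentiation of microfold (M) cells, the epithelial cells that carry antigen from the gut lumen to the lymphoid tissue beneath. The study asks what part ONECUT2 plays in RANKL-dependent differentiation of enterocytes and M cells. H3K27ac libraries held 5434172, 9160267 and 5578062 reads in regions in the control arm and 2745451, 3252533 and 3902301 in the RANKL arm.

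The first comparison asked where H3K27ac differed after the RANKL protocol. The M cell transcription factor gene Spib gained H3K27ac 4.49-fold and the RANKL receptor gene Tnfrsf11a 2.01-fold, while the stem cell gene Lgr5 lost it 3.18-fold (means of 3 against 3 libraries, errors given with each gene). The 2 regions of the M cell transcription factor gene Sox8 together gained it 11.3-fold, nearly all in the one 27.5 kb outside the gene. Onecut2 itself was not called. Of 54765 regions tested, 8120 were higher and 11520 lower with RANKL (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3 against 3 libraries), together 35.9% of regions. The balance depended on scaling, with 9915 higher and 9616 lower regions by library size only and 8404 and 8431 with the signal trend removed. At the level of genes, 4003 of 16035 were higher and 4310 lower, and by library size only 3448 and 5033. Changes of at least 1 on the log2 scale were called for 858 higher and 252 lower genes. At 57.2% of genes the 3 RANKL libraries lay on one side of the 3 control libraries, against 10% by chance. Against a minimum fold of 1.5, 3012 regions were higher and 2611 lower (3079 and 1438 with the signal trend removed), and 868 genes higher and 395 lower (884 and 351). The change followed signal strength, from a median log2 fold of 0.38 in the weakest 10% of regions to -0.29 in the strongest 10%. The RANKL libraries held 35.9% ± 0.8 of their reads in the strongest 10% of regions and the control libraries 38.5% ± 1.54 (SD, n = 3).

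**Figure D1:**
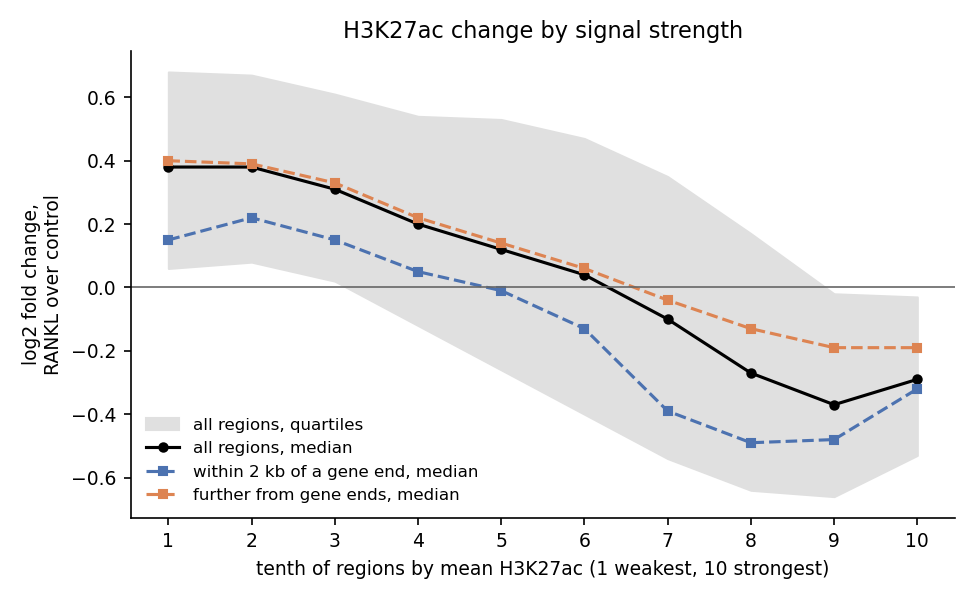
Median log2 fold change of H3K27ac (RANKL over control, vertical axis) for 10 equal groups of the 54765 tested regions ordered by mean signal (horizontal axis), for all regions with their quartiles (grey band) and for regions within 2 kb of a gene end or further away. Medians go from 0.38 in the weakest group to -0.29 in the strongest, and regions at gene ends lie below the others in each group.

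The region with the smallest adjusted p lay inside Ccdc33 on chromosome 9 (58101320 to 58103320), where H3K27ac rose from 4.29 ± 1.37 CPM in control to 125.8 ± 14.05 CPM with RANKL (SD, n = 3), a log2 fold of 4.78 ± 0.15 (SE). The next regions in this direction were an intergenic one on chromosome 3 (26530546 to 26532546, log2 fold 4.67 ± 0.16), one 12.6 kb from Gjb5 on chromosome 4 (127370728 to 127372728, 4.34 ± 0.15), one 51.2 kb from Eea1 on chromosome 10 (96096699 to 96098699, 4.56 ± 0.16) and one inside Rec114 on chromosome 9 (58708452 to 58710452, 4.09 ± 0.14). Among falling regions, the smallest adjusted p belonged to one inside Fam174b on chromosome 7 (73747909 to 73749909), with 72.5 ± 4.35 CPM in control and 11.4 ± 3.38 CPM with RANKL, a log2 fold of -2.68 ± 0.15. It was followed by regions inside Lgr5 on chromosome 10 (115585614 to 115587614, -2.93 ± 0.16), inside Ptpro on chromosome 6 (137442241 to 137444241, -2.61 ± 0.15), 48.3 kb from Gm5294 on chromosome 5 (138870038 to 138872038, -2.80 ± 0.16) and inside Slc35f2 on chromosome 9 (53770650 to 53772650, -2.88 ± 0.17). Adjusted p for these 10 regions ran from 1.11e-132 to 9.33e-53.

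Summed over their regions, the genes with the smallest adjusted p among those that rose were Ccdc33 (log2 fold 4.27 ± 0.10, SE), Cd247, which encodes the zeta chain of the T cell receptor complex (2.46 ± 0.07, and 1.18 at its gene ends), Xylt1, a xylosyltransferase of proteoglycan synthesis (2.53 ± 0.08), the connexin gene Gjb5 (3.68 ± 0.11), the peptidoglycan recognition gene Pglyrp2 (3.99 ± 0.12), Rec114 (3.79 ± 0.12), Cd200r2 (3.04 ± 0.11), Zbtb7c (1.84 ± 0.07) and the synaptotagmin gene Syt1 (1.85 ± 0.07). Gm38821 (2.04 ± 0.08) and Guca2b, which encodes uroguanylin (3.44 ± 0.13), tied for the last place. Adjusted p among these ranged from 3.19e-51 to 1.60e-38. The rise at Zbtb7c came from regions away from its ends, since with regions within 2 kb of the gene ends alone its log2 fold was -0.014 (adjusted p = 0.983). Among the genes that fell, Lgr5, the R-spondin receptor that marks intestinal stem cells, went from 239 ± 7.4 to 74.3 ± 9.09 CPM (SD, n = 3; log2 fold -1.67 ± 0.07, adjusted p = 3.48e-35). The others were Gm5294 (-1.70 ± 0.07), Cracdl (-1.19 ± 0.05), the glycosyltransferase gene Galnt7 (-1.62 ± 0.08), Bmp3 (-2.24 ± 0.12), the interleukin-22 receptor gene Il22ra1 (-1.85 ± 0.10), Fam174b (-1.66 ± 0.09), Slc12a3, a sodium chloride cotransporter (-1.35 ± 0.08), Ifi27 (-1.99 ± 0.12) and Myorg (-1.64 ± 0.10).

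M cell genes rose as a group. Of 30 tested, 23 were higher and 1 (Ncald, log2 fold -0.37) lower, both over all genes and adjusted over the list alone, with a median log2 fold of 1.04 (camera, adjusted p = 1.05e-19). The transcription factor Sox8, which M cells need to mature, went from 6.92 ± 1.66 to 80.4 ± 9.62 CPM (SD, n = 3), a log2 fold of 3.50 ± 0.14 (SE, adjusted p = 4.00e-36). Nearly all of that was in 1 region 27.5 kb outside the gene, from 4.35 ± 1.15 to 70.6 ± 8.19 CPM. The region in the gene went from 2.94 ± 0.81 to 5.71 ± 0.67 CPM (log2 fold 0.95 ± 0.40, adjusted p = 0.0463). With regions within 10 kb alone, the log2 fold of Sox8 was 1.14 (adjusted p = 0.0112). Spib, the transcription factor required for M cell differentiation, went from 8.50 ± 4.14 to 40.6 ± 7.26 CPM (2.17 ± 0.19, adjusted p = 2.49e-17). Tnfrsf11a, the receptor of RANKL, rose 2.01-fold (log2 fold 1.01 ± 0.06, adjusted p = 6.89e-26), and its decoy receptor gene Tnfrsf11b rose 2.90-fold (1.53 ± 0.07, adjusted p = 6.08e-34; 0.75 within 10 kb). The chemokine gene Ccl9 rose 8.55-fold (3.10 ± 0.16, adjusted p = 3.73e-29). Gp2, the uptake receptor of mature M cells, stood at 9.31 ± 0.77 CPM in control and 14.4 ± 3.26 with RANKL (log2 fold 0.63 ± 0.23, adjusted p = 0.0178). That call ended without control replicate 3 (adjusted p = 0.057), without RANKL replicate 2 (0.147) and with the signal trend removed (0.121). With an estimated correlation the M cell list kept its call (adjusted p = 0.0342), the only list to do so. Of the leukocyte markers, 6 of 9 were higher (4 without RANKL replicate 1, 4 of 8 within 10 kb). The 1 lower member was Itgax, not called lower without RANKL replicate 2. Their median log2 fold was 0.61, and they were not called as a list (camera, adjusted p = 0.345). With the signal trend removed, 4 of these leukocyte markers were higher and 1 lower (camera, adjusted p = 0.643).

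NF-κB family members, regulators and classical targets also rose, with 22 of 29 higher, 0 lower and 7 not called (camera, adjusted p = 2.94e-16). Adjusted p was 0.0598 with an estimated correlation. Adjusted over the list alone, 22 were higher and 1 (Rel) lower. The leukocyte markers, 6 of 9 of them higher (4 with the signal trend removed), were not called as a list (camera, adjusted p = 0.345). The adaptor gene Traf2 rose 3.71-fold (log2 fold 1.89 ± 0.07, SE, adjusted p = 5.03e-38), although its gene ends alone gave 0.24 (adjusted p = 0.0862). Nfkbia, which encodes the inhibitor IκBα, rose 2.41-fold (1.27 ± 0.05, adjusted p = 6.31e-36), and Tnfaip3, a target and inhibitor of NF-κB, rose with a log2 fold of 0.97 ± 0.05 (adjusted p = 2.08e-31).

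**Figure D2:**
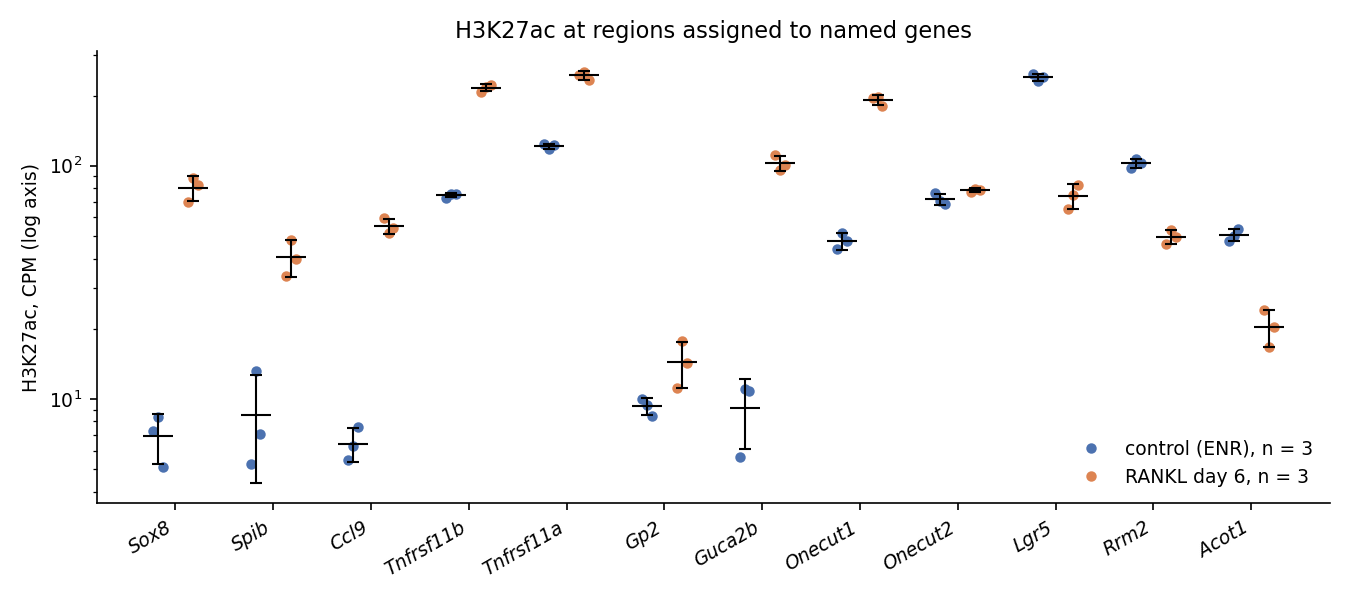
H3K27ac in TMM-normalised CPM (log axis) summed over the regions of 12 genes, with 1 point per library and the mean and SD of 3 control (blue) and 3 RANKL (orange) libraries. Sox8 goes from 6.92 to 80.4 CPM, and within it a region 27.5 kb outside the gene from 4.35 to 70.6 CPM. Lgr5 goes from 239 to 74.3 CPM, while the means at Onecut2 are 71.7 and 78.5 CPM.

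Of the absorptive lists, genes of the distal small intestine rose, with 6 of 11 higher and 1 lower (Tmigd1, not called lower without control replicate 1 or without RANKL replicate 3; camera, adjusted p = 0.00388; adjusted p = 0.147 with an estimated correlation). Guca2b rose 10.8-fold (9.15 ± 3.05 to 102.8 ± 7.77 CPM, SD, n = 3), Slc10a2, the ileal bile acid transporter, 2.21-fold (log2 fold 1.14 ± 0.09, adjusted p = 3.22e-20) and Clec2h 2.15-fold (1.10 ± 0.12, adjusted p = 1.23e-13). Genes of the proximal small intestine went both ways, with 4 of 13 higher and 3 (Creb3l3, Fabp1 and Gstm3) lower (adjusted p = 0.786). Apoa4, a chylomicron apolipoprotein, rose (0.89 ± 0.11), as did Adh6a (0.50 ± 0.17) and Gda (0.30 ± 0.08), and Gata4 was at 0.17 ± 0.04, which became -0.31 at its gene ends and 0.03 (adjusted p = 0.617) with the signal trend removed. General enterocyte genes had 9 of 36 higher and 10 lower (adjusted p = 0.895; 10 of 35 and 7 within 10 kb). Falling members included the monoamine oxidase gene Maoa (-1.19 ± 0.12), the villin gene Vil1 (-0.57 ± 0.09) and the fructose transporter gene Slc2a5 (-0.43 ± 0.08). Lipid metabolism genes fell, with 0 of 21 higher and 12 lower (camera, adjusted p = 0.00618; adjusted p = 0.238 with an estimated correlation). The acyl-CoA thioesterase gene Acot1 had a log2 fold of -1.32 ± 0.13, Cpt1a, which brings fatty acids into mitochondria, -0.57 ± 0.06 and the thiolase gene Acaa2 -0.74 ± 0.08. With regions at gene ends alone, the lipid list had an adjusted p of 0.062. Adjusted over the list alone, the counts of higher and lower genes were the same for the distal, proximal and lipid lists, and 11 enterocyte genes were lower.

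Cell cycle genes fell, with 10 of 18 lower and 1 (Mki67) higher (camera, adjusted p = 0.00704; adjusted p = 0.226 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, had a log2 fold of -1.04 ± 0.09 (SE), E2f1 of -1.24 ± 0.15 and the replication helicase gene Mcm6 of -1.33 ± 0.16. The stem cell and Wnt target list had 11 of 24 members lower and 5 higher and was not called (adjusted p = 0.213), but it was called lower with regions at gene ends alone (0.0111; other alternatives by camera, 0.0639 to 0.515). Besides Lgr5, the falling members included Rgmb (-0.50 ± 0.07) and Cd44 (-0.41 ± 0.06). Adjusted over the list alone, 12 were lower. In the fetal and regenerating epithelium list, 8 of 19 were higher and 3 (Ccn2, Krt7 and Ly6a) lower (camera, adjusted p = 0.00492; adjusted p = 0.147 with an estimated correlation). Mesothelin (Msln) rose 9.23-fold, the YAP target Ankrd1 5.76-fold and the interleukin-1 receptor antagonist gene Il1rn 1.93-fold. With regions within 10 kb alone, this list had an adjusted p of 0.152.

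The transcription factor Onecut2 itself was not called, with 71.7 ± 4.03 CPM in control and 78.5 ± 1.50 with RANKL (SD, n = 3; log2 fold 0.13 ± 0.09, SE, adjusted p = 0.194), and with the signal trend removed it passed (0.20, adjusted p = 0.0478). Its 4 regions were scaled separately from the gene counts. The one across the gene's lower coordinate end (chromosome 18, 64338957 to 64340957) fell, with a log2 fold of -0.38 ± 0.15 (adjusted p = 0.0344). With the signal trend removed, the log2 fold of this region of Onecut2 was -0.15. Its paralog Onecut1 rose 3.97-fold, from 47.7 ± 3.94 to 191 ± 9.0 CPM (log2 fold 1.99 ± 0.08, adjusted p = 2.77e-37). Most of that rise was in 1 region 18.7 kb outside the gene on chromosome 9 (74908394 to 74910394), from 26.1 ± 1.41 to 142.9 ± 8.01 CPM, and its gene ends alone gave a log2 fold of 0.321 (adjusted p = 0.527). Intestinal transcription factors had 10 of 29 higher and 6 lower, or 9 lower by library size only (camera, adjusted p = 0.190), with a rise at Hnf4g (0.64 ± 0.05, but -0.04 at its gene ends).

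Secretory and signalling lists were not called by camera, except the tuft cell list with regions at gene ends alone, which was higher (adjusted p = 0.00178; other alternatives by camera, 0.152 to 0.543). Enteroendocrine genes had 8 of 18 higher and 1 lower (Insm1, not called lower in 4 of the 6 fits without 1 library; 5 of 16 higher and 2 lower within 10 kb; adjusted p = 0.322), with Tac1 at a log2 fold of 1.31 ± 0.24 (SE) and Gip at 0.64 ± 0.14. Tuft cell genes had 7 of 17 higher and 3 (Pou2f3, Sucnr1 and Vav1) lower (adjusted p = 0.213), with Spib, Sh2d6 (0.70 ± 0.07) and Dclk1 (1.34 ± 0.14) rising. Goblet cell genes had 5 of 17 higher and 7 lower (adjusted p = 0.747), and Spdef (-0.87 ± 0.15, though 0.40 at its gene ends with an adjusted p of 0.33), Creb3l1 (-0.44 ± 0.08) and Creb3l4 (-0.99 ± 0.19) were lower. Paneth cell genes had 2 of 11 higher (Defa21 and Mmp7) and 3 lower (adjusted p = 0.895), led by Fgfr3 (-0.65 ± 0.11) and Ffar4 (-0.48 ± 0.10). The value for Pnliprp2 (-0.27 ± 0.11, adjusted p = 0.0379) lost its call without control replicate 3 (0.169) and without RANKL replicate 1, 2 or 3 (0.0748, 0.0869 and 0.0533). Notch genes had 2 of 15 higher (Dll1 and Rbpj, neither of them called within 10 kb) and 4 lower (adjusted p = 0.786), Notch3 at -0.82 ± 0.10, Notch1 at -0.62 ± 0.08, Nrarp at -0.63 ± 0.10 and Dll4 at -0.26 ± 0.08. Interferon and antigen presentation genes had 7 of 23 higher and 9 lower (adjusted p = 0.322; 4 higher and 11 lower without RANKL replicate 2, 6 and 6 without RANKL replicate 3), among them Irf9 (-1.87 ± 0.13), Irf7 (-1.11 ± 0.11) and Oas1a (-1.54 ± 0.17). Adjusted over the list alone, 8 of that list were higher and 10 lower, and the other lists of this paragraph kept their counts. In the goblet, Paneth, enterocyte and housekeeping lists, the median, the mean and the test differed in sign.

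Markers of cell types other than epithelium were included as a check. Mesenchymal markers had 5 of 12 higher and 0 lower (camera, adjusted p = 0.190; 3 higher adjusted over the list alone). There were 3 higher without RANKL replicate 1 or without RANKL replicate 3, and 3 higher and 1 lower by library size only or within 10 kb. Pdgfrb went from 11.3 ± 2.01 to 61.0 ± 3.95 CPM (SD, n = 3), Dcn from 10.0 ± 2.99 to 23.0 ± 0.63 and Myh11 from 10.3 ± 0.76 to 17.6 ± 4.42. The fold of Dcn turned to -0.62 with regions within 10 kb alone, and the call of Myh11 ended without RANKL replicate 1 (adjusted p = 0.0572). Endothelial markers had 6 of 11 higher and 3 (Eng, Pecam1 and Vwf) lower (adjusted p = 0.322; 3 of 10 higher and 2 lower within 10 kb), with Flt1 at a log2 fold of 1.39 ± 0.11 (SE; 0.67 within 10 kb), Tek at 1.05 ± 0.09 and Cdh5 at 0.69 ± 0.11, which was -0.10 within 10 kb. Of the leukocyte markers, Cd14 had a log2 fold of 0.58 ± 0.10, Cd52 of 1.28 ± 0.28 and Csf1r of 0.92 ± 0.26. Housekeeping genes had 4 of 13 higher, among them Gapdh (0.44 ± 0.08) and Eef1a1 (0.35 ± 0.07), and 4 lower, among them Tbp and Ywhaz (adjusted p = 0.984). The endothelial, leukocyte and housekeeping counts were the same adjusted over the list alone.

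**Figure D3:**
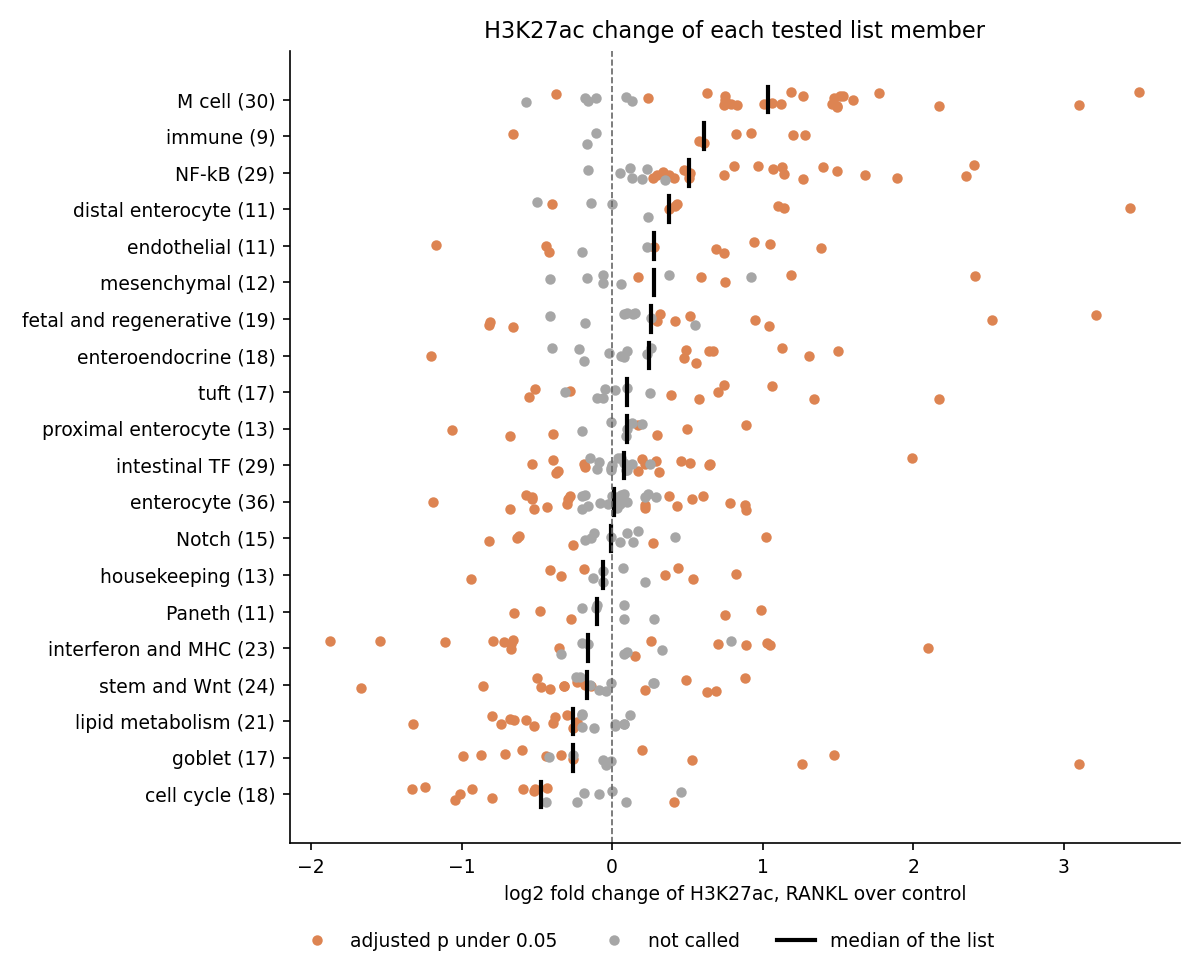
Log2 fold change of H3K27ac (RANKL over control, horizontal axis) for each tested gene of the 20 lists (rows, with the number of genes), in orange where the adjusted p over all genes was under 0.05 and in grey otherwise, with a black bar at the list's median. The M cell list has the highest median (1.04) and the cell cycle list the lowest (-0.48).

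The second comparison asked where ONECUT2 binding differed. In the authors' deposited table, nearly all listed sites were higher with RANKL, 7261 against 7 lower. The authors' deposited table gives a median log2 fold of 1.86 (3.64-fold) with quartiles of 1.48 and 2.34, and a median of 25.9 normalised reads per site with RANKL against 6.2 in control. At 59 sites the authors' deposited table lists the control mean at 0 on the log2 scale. Since 94.0% of the sites tested are listed, the direction covers most of the sites the authors tested. Of the sites, 50.6% overlapped a gene span and 16.3% lay within 2 kb of a gene end.

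By the authors' deposited table, the higher sites with the smallest FDR were 4.1 kb from Glg1 on chromosome 8 (111148819 to 111149219; log2 fold 3.60, FDR 2.04e-34), 8.7 kb from Kcna1 on chromosome 6 (126627397 to 126627797; 4.62) and 3.5 kb from Mef2c on chromosome 13 (83670559 to 83670959; 5.17). The next in the authors' deposited table lay inside Arsa (chromosome 15, 89477331 to 89477731; 3.86), Myo9b (chromosome 8, 71299809 to 71300209; 3.96), Slc35f4 (chromosome 14, 49458608 to 49459008; 5.07) and Man2a1 (chromosome 17, 64747281 to 64747681; 3.96), and 1 was intergenic on chromosome 4 (53273122 to 53273522; 3.82). The 7 lower sites in the authors' deposited table lay near or inside Rabep1 (-1.09), Stard13 (-1.15), E330021D16Rik (-0.86), the vitamin D receptor gene Vdr (-0.84), the desmoplakin gene Dsp (-0.99) and Rad51b (-0.39), with 1 intergenic on chromosome 2 (178594330 to 178594730; -0.57). In the authors' deposited table, the Onecut2 gene itself held a site on chromosome 18 (64344139 to 64344539) with a log2 fold of 2.58 (FDR 6.54e-23) and a weaker one at 1.01. Sites at the RANKL receptor gene Tnfrsf11a had log2 folds of 2.39 and 2.78, and a site 47.9 kb from Gp2 had 2.40, in the authors' deposited table.

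Higher ONECUT2 sites of the authors' deposited table were assigned to 19 of 36 enterocyte genes, where matched draws of genes gave 11.6 on average (two-sided permutation p = 0.01; adjusted over the 20 lists, 0.112). They included Rbp2, a retinol-binding protein (log2 fold 1.91), Krt20 (3.43) and the intestinal alkaline phosphatase gene Alpi (3.24) in the authors' deposited table. The sites of Krt20 and Alpi in the authors' deposited table lay 10.6 and 11.2 kb outside the genes. For proximal enterocyte genes the count was 9 of 13 against 4.59 (permutation p = 0.0112; adjusted, 0.112). Of M cell genes 13 of 30 were assigned a site, against 9.48 (adjusted p = 0.756), among them Cxcl16 (2.61) and Ccl20 (2.42), by the authors' deposited table. Of intestinal transcription factor genes 22 of 29 were, against 17.2 (adjusted p = 0.32), Gata4 at 2.11 and Ppara at 2.94 in the authors' deposited table. Stem cell and Wnt genes were assigned sites at 16 of 24, against 13.95 (adjusted p = 0.849), with Slc12a2 at 1.50, Rnf43 at 1.98 and Hopx at 1.79 in the authors' deposited table. The sites of Ppara and Slc12a2 in the authors' deposited table lay 58.9 and 17.4 kb outside the genes. None of the 20 lists passed adjustment.

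The third comparison asked whether H3K27ac changed where ONECUT2 bound. H3K27ac rose most where the ONECUT2 fold was greatest, although as a set the regions with a higher site passed only with the signal trend removed. Of the listed sites, 40.6% (2948) overlapped an H3K27ac region, against 6.7% for shifted sites (highest of 100 shifts, 7.5%). Of the 2920 tested regions with a higher site, 662 were higher for H3K27ac, 764 lower and 1494 not called. As a set they did not pass (camera, p = 0.265; p = 0.502 with an estimated correlation), and the test pointed up while their median log2 fold lay 0.02 below that of other regions (difference -0.024). With the signal trend removed the set passed (camera, p = 0.00374; p = 0.00613 with an estimated correlation). The 5 regions at lower ONECUT2 sites all had lower H3K27ac, with a median log2 fold of -1.30 (p = 2.39e-06; p = 0.0124 with an estimated correlation).

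Split by the ONECUT2 fold of the authors' deposited table, the 730 regions with the smallest fold had a median H3K27ac log2 fold of -0.27, with 6.3% of regions higher and 41.2% lower. The next groups of 730 had medians of -0.09, 0.06 and 0.64, and in the group with the largest fold 51.9% were higher and 7.9% lower. Across the 2920 regions, which are not independent replicates, the ONECUT2 fold and the H3K27ac fold had a Spearman correlation of 0.489, while the ONECUT2 read count with RANKL and the H3K27ac fold had one of -0.012. Of the 8 higher sites with the smallest FDR in the authors' deposited table, 6 lay in an H3K27ac region, with H3K27ac log2 folds of 3.08 (Glg1), 3.38 (Kcna1), 2.17 (Mef2c), 1.89 (Myo9b), 4.35 (Slc35f4) and 1.85 (chromosome 4), and those at Arsa and Man2a1 did not. Lgr5 had 3 listed sites in the authors' deposited table, 2 inside the gene with ONECUT2 log2 folds of 1.14 and 0.71, where H3K27ac had log2 folds of -2.18 and -2.49, and 1 at 36.8 kb with an ONECUT2 log2 fold of 1.70, where H3K27ac was at 0.51 (adjusted p = 0.0114). Regions called higher held a higher site more often than regions not called (8.2% against 4.3%; Fisher's exact test, odds ratio 2.0, 95% interval 1.82 to 2.2, p = 1.18e-42), as did regions called lower (6.6%; odds ratio 1.6, 1.46 to 1.75, p = 2e-23). Compared within 10 groups of like signal, the odds ratio was 1.47 for higher regions and turned to 0.79 for lower regions.

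**Figure D4:**
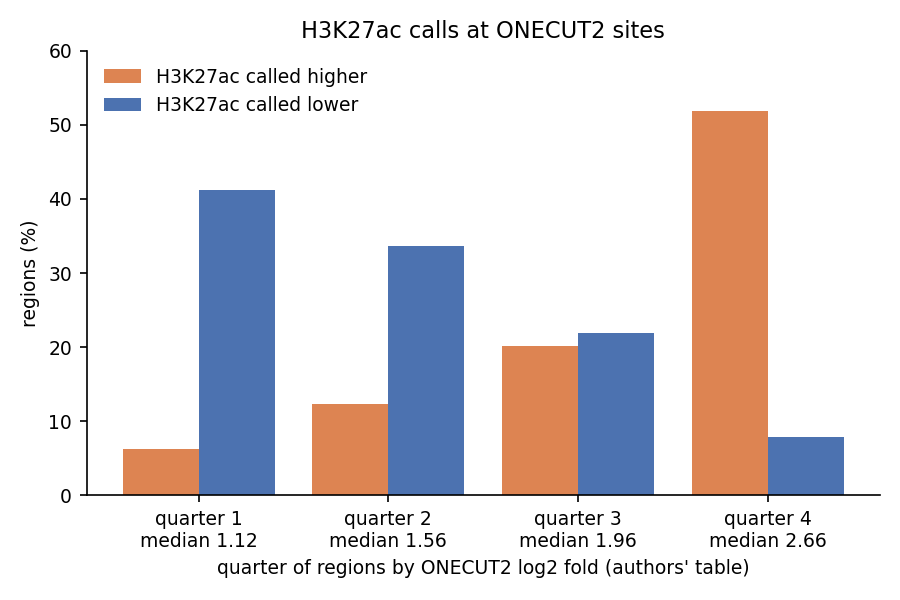
Share of regions (vertical axis, %) called higher (orange) or lower (blue) for H3K27ac in 4 groups of 730 tested regions that hold a higher ONECUT2 site, ordered by the ONECUT2 log2 fold in the authors' deposited table (horizontal axis, with each group's median). Higher calls go from 6.3% to 51.9% and lower calls from 41.2% to 7.9%.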

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

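Loess offsets for all but the region counts, or with a minimum fold or block, gene ends, groups of like signal, scores as deposited and thinned libraries were alternatives chosen after seeing the data. The counts of called regions ran from 16977 to 18236 and of genes from 7296 to 7913 when 1 library was left out, and stayed within 1.5 times of the main counts with DESeq2 (15806 regions), other scalings and filters, loess offsets (16835), thinned libraries (16755 regions, 7437 genes) and the deposited scores (16876). The replicate block gave 18806 regions and 8096 genes and changed the call of no list. Among the genes in the text it gave a call to H2-Ab1 (adjusted p = 0.0485) and took one from Msi1 (0.0531). Some member counts moved with it, among them the stem cell list, with 4 higher instead of 5. A minimum fold of 1.5 left 5623 regions (3012 higher, 2611 lower) and 1263 genes (868 and 395), and with loess offsets 4517 regions (3079 and 1438) and 1235 genes (884 and 351), since it sets a stricter question. Gene ends alone gave 5316 genes (2597 and 2719) of the 11928 with such a region. The 6 called lists became 1 with an estimated correlation, 16 with fry and 20 with fry's mixed test, which do not compare a list with other genes. Of 320 list results, 301 kept their side of the threshold, 7 lost and 12 gained a call and 0 reversed. Of 1212 results for 82 named genes, 1188 were the same, 17 lost and 1 gained a call and 6 reversed. The reversals were Cdh5 (-0.098) and Dcn (-0.616) within 10 kb, and Gata4 (-0.305), Hnf4g (-0.037), Spdef (0.395) and Zbtb7c (-0.014) at gene ends, where fewer regions are counted. ONECUT2 sites changed with RANKL numbered 6716 at an FDR under 0.01, 6943 with an absolute log2 fold of at least 1 and 2948 inside H3K27ac regions. For H3K27ac at ONECUT2 sites, p was 0.00374 with loess offsets and 0.00613 with an estimated correlation as well, against 0.19 to 0.464 with 1 library left out, and the cause was not tested. The odds ratio at lower regions became 0.79 within 10 groups of like signal, which compares regions of like signal. Small changes can be missed, since 21.2% of 1.5-fold changes in regions were recovered in simulation. That simulation changed far fewer regions than were called in the data and did not vary depth. The recovered share therefore need not hold for the data and is not tied to depth. GC corrections, motif variants and assignment to start sites were not run.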

Other observations

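Genes in this and the next paragraph were chosen after their values were seen. Members of the interferon and antigen presentation list, which was not called as a list, went both ways, and no test compared them with each other. Of MHC class II genes, Cd74, the invariant chain, rose from 4.84 ± 0.32 to 20.7 ± 6.46 CPM (SD, n = 3; edgeR, log2 fold 2.10 ± 0.25, SE, adjusted p = 1.09e-11), as did H2-Eb1 (1.05 ± 0.13, adjusted p = 2.85e-11) and the class II transactivator gene Ciita (0.70 ± 0.10, adjusted p = 5.17e-09), although Ciita was at 0.12 and not called with regions within 10 kb alone. H2-Aa (0.89 ± 0.36, adjusted p = 0.035) was called in 10 of 15 settings and lost its call without control replicate 1 and without RANKL replicate 1 or 2, and H2-Ab1 was at 0.79 ± 0.36 and did not pass (adjusted p = 0.0588), but was called with the replicate block (0.0485), without control replicate 2 (0.0191) and at its gene ends (0.024). Leukocyte markers, 6 of 9 of them higher (4 with the signal trend removed), were not called as a list (camera, adjusted p = 0.345). The peptide transporter gene Tap2 of the class I pathway rose (1.03 ± 0.14), while the immunoproteasome gene Psmb9 fell (-0.72 ± 0.11). Of interferon response genes, Irf9, Irf7 and Oas1a fell and Irf1 rose (0.15 ± 0.06, adjusted p = 0.0202; 0.305 with the signal trend removed). Among goblet cell genes, Clca1 (1.47 ± 0.08) and Tff3 (1.26 ± 0.18) rose while Spdef and Creb3l4 fell.

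Members of the stem cell list also went both ways. Ascl2, a transcription factor of stem cells, had a log2 fold of -0.86 ± 0.15 (SE), in the direction of Lgr5, while Tnfrsf19 rose (0.88 ± 0.08). Cdk6 (0.63 ± 0.05) and the Wnt target Axin2 (0.49 ± 0.05) were higher, but Axin2 was at -0.05 at its gene ends (adjusted p = 0.697). Msi1 was at 0.22 ± 0.10 (edgeR, adjusted p = 0.0459) and was called in 7 of 15 settings. Olfm4 showed 2 directions, with 0.69 ± 0.09 over its 5 regions and -1.0 at its gene ends (adjusted p = 8.92e-06). In the Notch list, Rbpj rose (1.02 ± 0.06) against the falls of Notch1 and Notch3, though not with regions within 10 kb alone (-0.04).

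The tests in the rest of this part were chosen after the results they bear on were seen, except the test of gene ends in the next sentences. Weakly acetylated regions rose and strongly acetylated regions fell with RANKL, which lower signal over background in the RANKL libraries could produce. That explanation was taken to need strong regions to fall alike wherever they lie. In the strongest 10% of regions the median at gene ends was lower than elsewhere by more than the 0.1 allowed beforehand. The difference was -0.13, with a 95% bootstrap interval over regions of -0.16 to -0.10. To compare libraries, each region's log2 signal was centred on its mean over the 6 libraries. On that scale the gap between the classes was -0.07 in each RANKL library and 0.06 to 0.07 in the control libraries. Centring makes the arms near mirror images, so the opposite signs add no support and do not rank the classes by signal. Gene ends also lay lower in the weakest 10% (median 0.15 against 0.40), and the classes were not matched on background. The gap therefore cannot decide on signal over background, which stays open as a source of the trend. The trend is not the whole source of the 2857 lower calls in the strongest 10%, of which 58.1% remained with it removed. This says nothing on where the trend comes from. A global change of acetylation after the valproic acid treatment is open and untested, since the arms differ in it.

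Nearly all listed ONECUT2 sites rose, and 1 scaling factor between the arms, from library scaling or the yield of the immunoprecipitation, cannot be told apart from more binding, because only 0.1% of listed sites fell and the table holds means per condition. Library scaling moves all sites alike, whereas 21.3% of sites lay outside the 95% interval around the median that their implied standard errors give. By chance about 5% would, although these errors were derived from p-values of listed sites alone and are approximate. They also join those p-values to differences of means (median 1.99), which are larger than the listed folds (median 1.86). As far as they hold, sites differed by more than 1 common factor and noise would give. A common factor cannot set sites apart, so library scaling stays open as a source of the shared rise. A difference in yield need not move all sites alike where their background differs, so these values do not decide on it. Of the 2920 tested regions with a higher site, 26.2% were called lower for H3K27ac (21.5% by library size only, 15.8% with the trend removed). Among all 54765 tested regions, 21% were called lower (9616 and 8431 regions with these 2 scalings). All tested regions would thus pass the bar of 10%, which was set after these values were seen. Rising acetylation at the sites relative to other regions is argued against only at the regions called lower, where ONECUT2 rose without it. It stays open for the others. A rise common to all regions would be lost in scaling and stays open. More binding of ONECUT2 with RANKL is a biological explanation, and it remains an open hypothesis.

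The ONECUT2 fold was greater where H3K27ac rose, with a median log2 fold of 2.33 at sites in higher regions and 1.49 at sites in lower ones. The ONECUT2 read count with RANKL did not follow the H3K27ac fold (Spearman correlation -0.012 over 2920 regions). A candidate explanation is unspecific recovery of newly acetylated chromatin by the ONECUT2 antibody. If strong, it was taken to place sites in most of the strong regions called higher, which need not be newly acetylated. Of the 1262 higher regions in the strongest 10% of the RANKL libraries, 12.8% held a higher site. Of the 567 among them with a log2 fold of at least 1, 13.6% did. Among all tested regions, which are not matched to these on signal, 5.3% held a higher site. This argues only against a recovery strong enough to list most of the strong regions called higher. A weaker recovery, which could raise the fold without a listed site in most of them, stays open. A joint gain of binding and acetylation at some enhancers is a hypothesis that these libraries do not test further.

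In the comparison of H3K27ac, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, the 1 with as many calls, called 19640 regions and 8313 genes, and the highest of the others called 0 of each by edgeR, with at most 1134 regions and 227 genes at an unadjusted p under 0.05. Each of the other splits mixes both arms in its groups. The difference between the arms then adds to the spread within groups, so few calls would be seen whatever its source.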
